A study of Sus scrofa with 8 samples.

How the data were processed

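Total RNA from the longissimus dorsi, the long muscle of the back, was hybridised to 8 one-colour Affymetrix porcine arrays, 4 from Korean native pigs aged 7 months and 4 from Yorkshire pigs aged 6 months. The labels call the arrays of a breed biological replicates numbered 1 to 4. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols.

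The deposited values are linear intensity values, 1 per probe set and array. The software GCOS 1.3 is named in the submitters' processing notes. The summarisation method, the scaling target and any filter are not given in the sources used here, and no detection calls were used. On each array the mean signal without the highest and lowest 2% of values was between 500.1 and 500.2, so the deposited intensity values had been scaled to a common level per array. Scaling of this kind removes any difference in total RNA signal between arrays, so every change below is relative to the other probe sets of the same array. The value table held 24123 probe sets, and it had 0 value columns beyond those of the 8 arrays. No 2 arrays held identical values, and the highest correlation between arrays was 0.949.

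Gene names were taken from GEO's platform annotation of the probe sets, which can be old. It gave exactly 1 gene symbol for 10099 probe sets and several symbols for 198, while 13826 probe sets were unnamed here. Of the probe sets with 1 symbol, 9989 were found by gene number in the gene table of the Sscrofa11.1 assembly, and 0 symbols changed. The genome build of the array design is not given in the sources used here, so no positions are reported. No gene was named from a probe set with several symbols.

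Each value was transformed to log2(signal + 32), and a fold change is therefore on that scale, which understates the change of dim probe sets. The 124 control probe sets were left out of the tests, as were the dimmest 40% of the rest by mean over all arrays, which left 14399 probe sets. This limit lay near a signal of 98.6, just above the 95th percentile of 91.5 for the 23 negative control probe sets. The median log2 signal of the arrays differed by at most 0.379, below the limit of 0.5 set for further normalisation, so the deposited scaling was kept. For arrays the number of arrays limits the precision: the median standard error of a log2 change was 0.283, and its 95% confidence interval reached a median of 0.617 to each side.

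Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on all 8 arrays, without covariates. Changes are Korean native pig minus Yorkshire, p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and the threshold was an adjusted p of 0.05. A gene was represented by its probe set of highest mean signal among those with 1 symbol, which gave 5331 genes from 7019 probe sets. On data simulated from the means and spreads of these arrays, with 200 of 14399 probe sets changed in each of 10 runs, the test recovered 27.8% of log2 changes of 1, 78.4% of changes of 2, 94.4% of changes of 3 and 98.0% of changes of 4. Of its calls 4.68% were false. The simulated noise was independent between probe sets, and the shares hold for that number of changed probe sets, since the adjusted threshold is stricter where fewer change.

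The 26 gene lists were written before the data were examined, from general knowledge of muscle and of the other cell types that a muscle piece can hold. Of these, 25 had at least 5 tested genes. The list of red cell markers had 3 and was not tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists. Camera with an estimated correlation and limma's fry were run as alternatives. In simulated data without correlation between genes, camera found a list of 20 genes shifted by 0.5 in 10 of 10 runs and called 0 of 240 unshifted lists. Genes of a real list can vary together, so these rates need not hold for the lists tested here.

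The rule for named genes was fixed at the same time. It took up to 12 genes in each direction that passed the threshold without overlap between breeds, filled to 5 by smallest p where fewer passed. From each list it took up to 4 members that passed, or the 2 of smallest p where none did, and from a list of growth and meat quality genes all members that passed, or the 4 of smallest p. It also took up to 2 unnamed probe sets in each direction past the threshold. No gene passed, so each gene named below was taken by its p and is given as a value. Genes named outside the rule were chosen after their values were seen, and this is said where they appear.

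RNA and labelling quality was read from control probe sets for the 3' and 5' ends of GAPDH, actin and EF1A, and of bacterial transcripts spiked in before labelling. Differences between breeds in such array measures were tested by exact two-sided permutation over the 70 labellings of the arrays, where the smallest possible p is 0.0286. Separation of the arrays by breed was tested over the 35 splits into 4 and 4, where the smallest possible p is also 0.0286.

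The alternatives changed 1 choice at a time. They were a value of 1 or 128 added before log2, no filter or a filter on the dimmest 60%, quantile normalisation, arrays centred on their median, eBayes without trend or with robust estimation, array weights, the replicate number as a block, the mean over a gene's probe sets, adjusted p thresholds of 0.01 and 0.1, other distances between arrays, single control genes, and each array left out in turn. Added after the data were examined were a block for the brightness of the hybridisation controls, the 3' to 5' ratio as a covariate, leaving out both arrays of high ratio, ranking each list among the 35 splits, the count of probe sets at an unadjusted p under 0.05, and the spiked controls as a measure of quality. The labels give no batch, slide, date, sex or litter.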

Results

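Gene expression in skeletal muscle was compared between Korean native pigs and Yorkshire pigs. The stated purpose was to find genes expressed differently in the muscle of these breeds. Muscle between the seventh and ninth ribs was profiled on 1 array per replicate, with 4 replicates per breed. The Korean native pigs were 7 months old and the Yorkshire pigs 6 months old, so breed and age cannot be told apart in any comparison below. The median signal per array ranged from 135.8 to 185.3.

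The muscle profiles did not separate by breed. The correlation of log2 signal between 2 arrays, taken across probe sets, which are not independent replicates, had a median of 0.918 within breeds and 0.920 between breeds. The mean distance (1 minus r) was 0.0812 between breeds and 0.0831 within breeds, and 21 of the 35 splits of the arrays gave a difference at least as large (exact permutation test, one-sided p = 0.6). The first principal component held 27.4% of the variance and the second 18.7%.

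**Figure D1:**
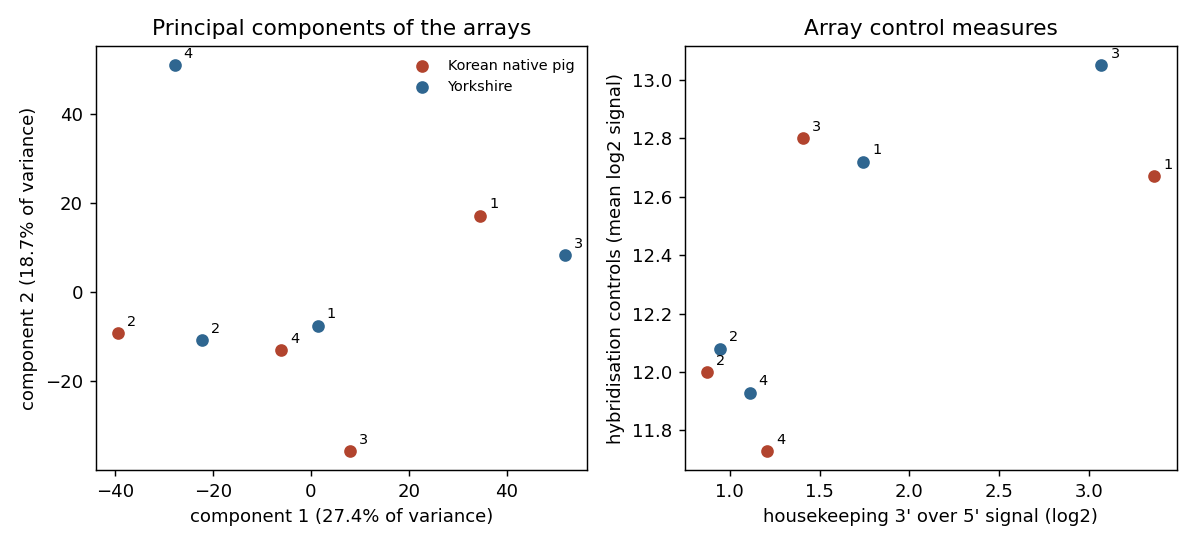
Left, the 8 arrays on the first and second principal components of log2(signal + 32), with the share of variance on each axis; right, the mean log2 ratio of 3' over 5' signal of the housekeeping controls (x axis) against the mean log2 signal of the hybridisation controls (y axis). Points are arrays, coloured by breed and numbered by replicate; Korean native pig 1 (3.37) and Yorkshire 3 (3.07) have the highest ratios, and both breeds have 2 arrays with bright and 2 with dim hybridisation controls.

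Control probe sets showed differences between arrays that were balanced over the breeds. The 3' signal of the housekeeping transcripts exceeded the 5' signal by 1.71 ± 1.12 log2 units in Korean native pigs and 1.72 ± 0.97 in Yorkshire pigs (SD, n = 4; exact permutation test, two-sided p = 1). Korean native pig 1 and Yorkshire 3 stood apart at 3.37 and 3.07, against 0.88 to 1.74 on the other 6 arrays. The hybridisation controls were bright, at 12.67 to 13.05 log2 units, on replicates 1 and 3 of both breeds and dim, at 11.73 to 12.08, on replicates 2 and 4. The bright arrays also had the higher 3' to 5' ratios, 1.41 to 3.37 against 0.88 to 1.21 on the dim ones. The first principal component followed both measures, at 1.41 to 51.86 on the bright arrays and -39.41 to -6.14 on the dim ones.

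No gene passed the adjusted threshold, and the genes of lowest p were lower in Korean native pigs. The lowest was CREM, a transcription factor that responds to cyclic AMP, with a signal of 1384 ± 442.7 in Korean native pigs and 6265 ± 2531 in Yorkshire pigs (SD, n = 4). Its log2 change was -2.11 (SE 0.31, 95% interval -2.78 to -1.43), a 4.31-fold difference, with limma adjusted p = 0.281. NR4A3, an orphan nuclear receptor induced in muscle by exercise and adrenergic stimulation, had a signal of 188.9 ± 129.1 against 1514 ± 913.4 (SD, n = 4). Its log2 change was -2.79 (SE 0.46, 95% interval -3.80 to -1.79), with limma adjusted p = 0.298. With the replicate number as a block NR4A3 passed (limma adjusted p = 0.00943). The labels do not say that the numbers pair arrays of both breeds, and the values could not settle it. The numbers do follow the brightness of the hybridisation controls. NR4A3 signals in Korean native pigs 1 and 2, 87.0 and 92.2, lay near the 95th percentile of the negative controls, 91.5, so the size of its change is uncertain. For both genes the signal of all 4 Korean native pig arrays lay below that of all 4 Yorkshire arrays.

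A further CREM probe set had a log2 change of -1.77 and another 0.19, both given after their values were seen. Within the arrays of bright hybridisation controls, 2 per breed, the log2 change was -2.87 for CREM and -3.18 for NR4A3. Within those of dim controls, also 2 per breed, it was -1.35 and -2.41.

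The next 3 lower genes were RCAN1, an inhibitor of calcineurin, at -1.36, the serine protease gene PRSS23 at -0.85, and DHDH at -1.30. Higher in Korean native pigs, again without passing, were GCLM at 1.04, the modifier subunit of the enzyme that starts glutathione synthesis, and ASB3 at 1.13. The remaining 3 were POLR1D at 0.70, the clock gene PER1 at 0.88 and PDE4C, a phosphodiesterase of cyclic AMP, at 0.80. All 8 had limma adjusted p = 0.999, and in each the 4 values of one breed lay above the 4 of the other. A second probe set of ASB3 was at 0.03, one of POLR1D at 0.21 and one of RCAN1 at -0.90. Within the bright and the dim arrays the values were -2.04 and -0.68 for RCAN1, -1.08 and -0.63 for PRSS23, and -1.78 and -0.83 for DHDH. They were 1.14 and 0.94 for GCLM, 0.96 and 1.29 for ASB3, 0.64 and 0.76 for POLR1D, 0.65 and 1.10 for PER1, and 0.93 and 0.67 for PDE4C.

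**Figure D2:**
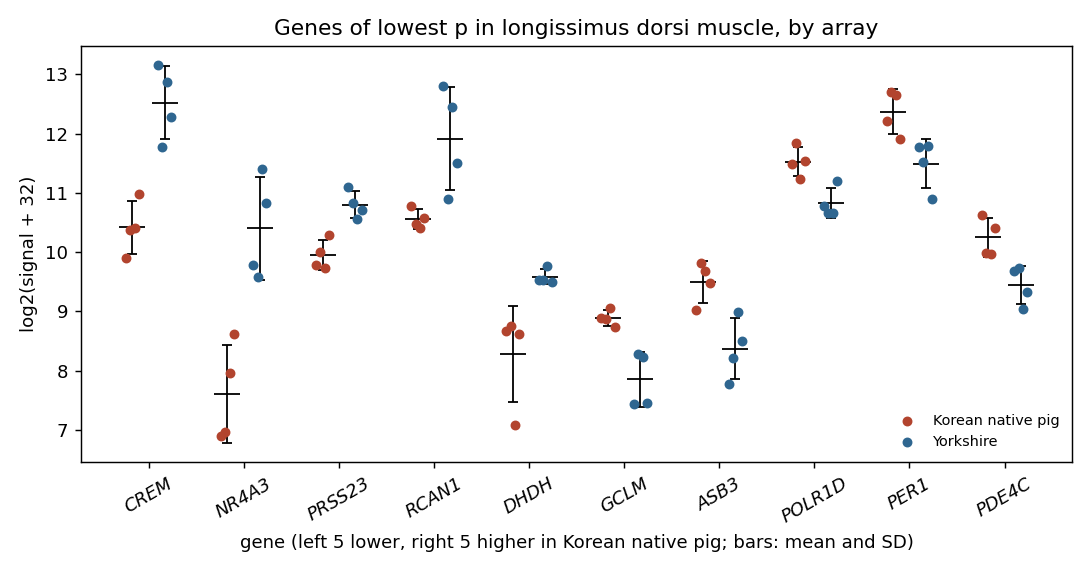
Log2(signal + 32) of the 10 named genes of lowest p (y axis), 5 lower and 5 higher in Korean native pigs (x axis). Points are arrays, 4 per breed, with the mean and SD as a line and bars; in each gene the breeds do not overlap, and NR4A3 has the largest log2 change, -2.79.

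By limma, 0 of 14399 probe sets and 0 of 5331 genes passed, with a smallest adjusted p of 0.281. At an unadjusted p under 0.05 there were 570 probe sets, 289 higher and 281 lower. Independent probe sets without any difference would give 719.95 on average, but the other splits of the arrays gave 274 to 1680. Among genes 183 were at an unadjusted p under 0.05, 93 higher and 90 lower. The breeds did not overlap in 369 probe sets, or 2.56%, where chance gives 2.86%. With the brightness of the hybridisation controls as a block, 0 probe sets passed, and within the bright and the dim arrays 0 passed, with 397 and 527 at an unadjusted p under 0.05. On simulated arrays the same test recovered 78.4% of log2 changes of 2 and 27.8% of changes of 1, so changes near 2-fold were mostly not detectable with 4 arrays per breed. These shares hold for 200 changed probe sets with independent noise. Where fewer probe sets change the adjusted threshold is stricter, and CREM at -2.11 and NR4A3 at -2.79 did not pass here.

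Of the 25 gene lists tested, camera with the preset correlation called 4, all lower in Korean native pigs. These held fast fibre genes, genes of glycolysis and glycogen, collagen and matrix genes, and genes of the respiratory chain. No list was called with an estimated correlation, where the smallest adjusted p was 0.755, and none by fry, where it was 0.904. At an unadjusted p under 0.05 these tests gave 8 lists with the preset correlation, 0 with the estimated one and 0 by fry. Calls given below with arrays left out or under other settings of the fit are all by camera with the preset correlation. With that test 29 of the 35 splits of the arrays called 4 or more lists, so such calls can arise by chance.

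**Figure D3:**
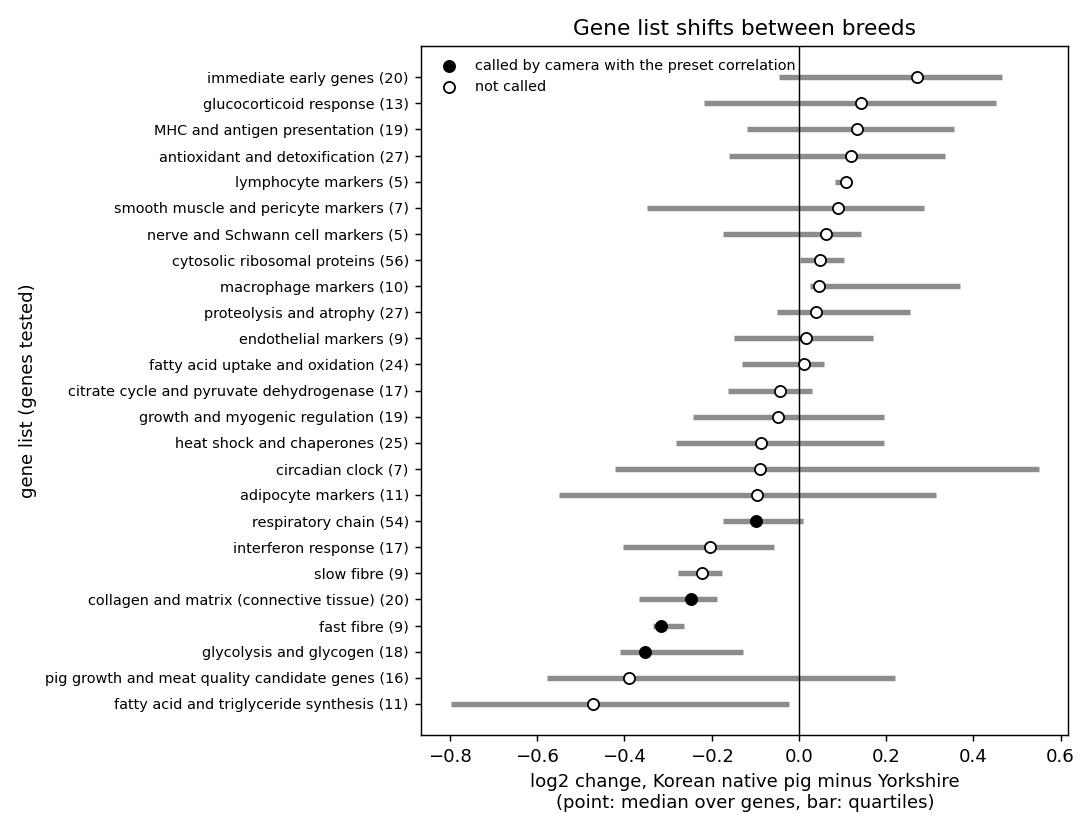
Median log2 change, Korean native pig minus Yorkshire, of the tested genes of each of 25 lists (points, x axis), with quartiles over genes as bars. Lists are on the y axis with their number of tested genes; filled points are the 4 lists called by camera with the preset correlation, from -0.35 for glycolysis and glycogen to -0.10 for the respiratory chain, none of which was called with an estimated correlation.

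Muscle fibre and energy genes had mostly negative changes in Korean native pigs, none passing alone. All 9 fast fibre genes were below 0, with a median of -0.32 (camera adjusted p = 0.00401; adjusted p = 0.755 with an estimated correlation). They included TNNC2, the fast troponin C, at -0.42 (-0.23 without Yorkshire 4) and MYL1 at -0.33 (-0.19 without Korean native pig 4). Of 18 genes of glycolysis and glycogen, 15 were below 0, with a median of -0.35 (camera adjusted p = 0.00351; adjusted p = 0.812 with an estimated correlation), among them LDHA and ENO3, both at -0.41 (ENO3 -0.25 without Yorkshire 4). Of 9 slow fibre genes 8 were below 0, with a median of -0.22 (camera adjusted p = 0.0847, or 0.843 with an estimated correlation). They included MYL2 at -0.24 (-0.09 without Korean native pig 4) and the slow myosin MYH7 at -0.28 (-0.10 without Yorkshire 3). Without Korean native pig 3 these were at -0.40 and -0.43.

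Among 54 genes of the respiratory chain 39 were below 0, with a median of -0.10 (camera adjusted p = 0.0475; adjusted p = 0.843 with an estimated correlation). ATP5B and ATP5A1, subunits of the ATP synthase, were at -0.26 and -0.32, the latter -0.20 without Yorkshire 3. The list of citrate cycle and pyruvate dehydrogenase genes was not called (median -0.04, 11 of 17 below 0), with SUCLA2 at -0.27 and PC at -0.39 (-0.23 without Korean native pig 3). The list median was 0.02 without Korean native pig 4 and -0.11 without Korean native pig 2.

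Single arrays decided these calls. Without Yorkshire 4 the fast fibre median was -0.14 (adjusted p = 0.184) and the glycolysis median -0.14 (adjusted p = 0.255), and without Korean native pig 4 they were -0.22 and -0.23 (adjusted p = 0.0611 for both). Without Korean native pig 3 the median of glycolysis and glycogen was -0.15, and the list was still called (adjusted p = 0.0318). With quantile normalisation they were -0.01 (adjusted p = 0.662) and -0.13 (adjusted p = 0.0944). The respiratory chain call was lost without Korean native pig 3 or 4 (adjusted p = 0.0824 and 0.714), without Yorkshire 2, 3 or 4 (0.297, 0.224 and 0.0708) and under 8 other settings of the fit, which the closing section gives. Its median was -0.02 without Korean native pig 4 and -0.18 without Yorkshire 1. The slow fibre list was called without Korean native pig 1 or 3 (medians -0.33 and -0.40, adjusted p = 0.0284 and 0.00294), without Yorkshire 1 or 2 (0.0258 and 0.0436) and with the hybridisation controls as a block (0.0489), but its median was -0.07 without Yorkshire 3 (adjusted p = 0.698). Within the bright arrays the medians were -0.02 for fast fibre, -0.04 for glycolysis, 0.03 for slow fibre and -0.02 for the respiratory chain, and within the dim arrays -0.61, -0.57, -0.57 and -0.16.

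Lipid genes did not pass as lists. Fatty acid and triglyceride synthesis had the lowest median of any list, -0.47, with 8 of 11 genes below 0 (camera adjusted p = 0.0847). GPAM, which catalyses the first step of glycerolipid synthesis, was at -0.81, and the fatty acid elongase ELOVL6 at -1.31 (SE 0.74), with 3 more ELOVL6 probe sets at -0.98, -0.82 and -1.09. A second GPAM probe set was at -0.17, and the GPAM signal of 68.1 in Korean native pig 2 lay below the 91.5 of the negative controls. Without Korean native pig 1 this list was called (median -0.65, adjusted p = 0.0114), as it was with arrays centred on their median (-0.40, adjusted p = 0.0270), but without Korean native pig 3 its median was -0.25, and without Korean native pig 4 -0.76. ELOVL6 was at -0.70 without Korean native pig 2 and -2.05 without Korean native pig 1. Genes of fatty acid uptake and oxidation had a median of 0.01 but a mean of -0.09, and camera's direction was down (adjusted p = 0.661). PPARGC1A, a coactivator of mitochondrial biogenesis, was at -0.96 (SE 0.41), or -0.49 without Yorkshire 3, and ECHS1 at -0.33. Without Korean native pig 3 the oxidation list had a median of -0.13 and was called (adjusted p = 0.0304), and its median was -0.08 without Yorkshire 1, -0.01 without Yorkshire 2, -0.06 without Yorkshire 4 and 0.11 without Korean native pig 4. Within the bright and the dim arrays the synthesis list was at -0.18 and -0.41 and the oxidation list at 0.11 and -0.12. Adipocyte markers had a median of -0.10 with 7 of 11 below 0, or -0.24 without Korean native pig 3. Of these, CFD was at 0.70, or 0.44 without Korean native pig 1, and CIDEA at -0.79, or -0.42 without Korean native pig 2, where its signal of 34.6 was also below 91.5 (adjusted p of the list = 0.511).

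Of 20 collagen and matrix genes, markers of connective tissue, 18 were below 0, with a median of -0.25 (camera adjusted p = 0.00351; adjusted p = 0.755 with an estimated correlation). FBN1, which encodes fibrillin, was at -0.52, or -0.32 without Yorkshire 3, and COL5A1 at -0.39, or -0.17 without Korean native pig 3, while a second COL5A1 probe set was at -0.03. The call was lost without Korean native pig 3 (median -0.16, adjusted p = 0.112) and without Yorkshire 3 (-0.20, adjusted p = 0.0535). The median was -0.39 without Korean native pig 1, and it was -0.50 within the bright arrays and -0.13 within the dim ones.

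Markers of vessels and nerve were not called. The 9 endothelial genes had a median of 0.02 and a mean of -0.05, with EGFL7 at -0.62 and ENG at -0.64. That median was -0.05 without Korean native pig 3, -0.01 without Korean native pig 4, -0.05 without Yorkshire 1, -0.02 without Yorkshire 2, -0.09 without Yorkshire 4 and 0.06 without Yorkshire 3. For ENG, 2 Korean native pig arrays had signals of 71.3 and 90.6, below the 91.5 of the negative controls. The 7 smooth muscle and pericyte genes had a median of 0.09 and a mean of -0.01, with SMTN at 0.41 and TAGLN at -0.38, and a second SMTN probe set was at -0.25. The list median was -0.03 without Korean native pig 1, -0.01 without Yorkshire 4 and 0.17 without Yorkshire 3. The 5 nerve and Schwann cell genes had a median of 0.06, with MBP, a myelin protein gene, at 1.03 and S100B at -0.17 (-0.01 without Yorkshire 2, -0.30 without Yorkshire 1). Other MBP probe sets were at 0.87, 0.67 and 0.03, and the list median was -0.20 without Korean native pig 4, -0.05 without Yorkshire 1, -0.02 without Yorkshire 2 and 0.32 without Korean native pig 2. Of the red cell markers ALAS2 was at -0.47 (-0.23 without Korean native pig 3, -0.86 without Korean native pig 1) and HBM at 0.28 (0.01 without Yorkshire 1, 0.43 without Yorkshire 2), and the 3 tested genes had a median of 0.07. In the arrays whose removal moved these genes nearest to 0 their signals, 81.3 and 82.7, were below 91.5.

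Genes of protein turnover and growth went both ways. Of 27 genes of proteolysis and atrophy 16 were above 0, with a median of 0.04 (adjusted p = 0.418), or 0.01 without Yorkshire 1 and 0.08 without Korean native pig 1. FBXO32, the muscle ubiquitin ligase atrogin, was at 1.06 (SE 0.38), with a second probe set at 1.05, and the calpain gene CAPN2 at -0.52 (SE 0.18). The growth and myogenic list had a median of -0.05, with IGF1R at 0.44 and MEF2D at 0.26 (adjusted p = 0.953). MEF2D was at 0.17 without Korean native pig 1 and 0.41 without Yorkshire 2, and IGF1R signals of 79.9 to 90.7 in 3 Yorkshire arrays lay below the 91.5 of the negative controls. The list median was 0.00 (0.00405) without Korean native pig 4, 0.06 without Yorkshire 2 and -0.08 without Yorkshire 3. Of 56 ribosomal protein genes 42 were above 0, with a median of 0.05 and RPL37 at 0.65 and RPL23 at 0.29, or 0.18 without Yorkshire 3 (adjusted p of the list = 0.0847). This ribosomal list was called higher without Korean native pig 3 or 4 (adjusted p = 0.0318 and 0.00152), without Yorkshire 4 (3.34e-07), with quantile normalisation (3.16e-05) and with arrays centred on their median (0.0411). Its median was -0.01 without Korean native pig 1 and -0.04 without both arrays of high 3' to 5' ratio.

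Stress and signalling lists were not called. Of 25 heat shock and chaperone genes 13 were below 0 (median -0.09, adjusted p = 0.425), with the co-chaperone BAG3 at -1.35 (SE 0.43), its second probe set at -1.06, and HSPB8 at -0.69, or -0.44 without Yorkshire 4. Without Yorkshire 2 this list was called lower (median -0.20, adjusted p = 0.00348), and without Korean native pig 4 its median was 0.01. Of 20 immediate early genes 15 were above 0, with a median of 0.27, and EGR1 at 1.17 (SE 0.41), while NR4A3 was among the 5 below 0 (adjusted p of the list = 0.250). A second EGR1 probe set was at 0.31, and without Yorkshire 1 the list was called higher (median 0.34, adjusted p = 0.0338), while without Yorkshire 2 its median was 0.05. Circadian clock genes had a median of -0.09 and a mean of -0.04, against camera's direction of up (adjusted p = 0.957), with PER1 at 0.88 and NFIL3 at -1.33. The clock median was 0.19 without Korean native pig 1, 0.07 without Korean native pig 2, 0.14 without Yorkshire 4 and -0.30 without Korean native pig 3. Within the bright and the dim arrays NFIL3 was at -1.39 and -1.26, EGR1 at 1.17 and 1.18, and BAG3 at -1.92 and -0.77.

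Adjusted over the list alone, 1 of the 20 immediate early genes passed, NR4A3 (0.00123), and 2 of the 7 clock genes, PER1 (0.0289) and NFIL3 (0.0491). This adjustment was not made over the 25 lists, so such passes can arise by chance. The NFIL3 signals of the breeds overlapped, with 1262 in Korean native pig 4 above Yorkshire 1, 2 and 3 (802.3, 987.6 and 939.8). In the other 23 lists 0 genes passed when adjusted over the list alone, and over all genes tested 0 passed in any list.

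The glucocorticoid response list had a median of 0.14, with PER1 at 0.88 and SESN1 at 0.55, or 0.29 without Korean native pig 3 (adjusted p of the list = 0.294). Its median was -0.04 without Korean native pig 2, -0.02 without Korean native pig 3 and 0.23 without Yorkshire 2. Antioxidant and detoxification genes had a median of 0.12, with 16 of 27 above 0, GCLM at 1.04 and thioredoxin, TXN, at 0.40 (adjusted p = 0.0962). This list was called higher without Yorkshire 2 (median 0.20, adjusted p = 0.0353), while without Yorkshire 1 its median was 0.01.

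Immune lists were not called, and leaving out single arrays turned the direction of each. Of 19 genes of MHC and antigen presentation 13 were above 0, with a median of 0.13 (adjusted p = 0.220). SLA-DQA1 was at 0.89. CIITA, the transactivator of class II genes, was at 1.34 (SE 0.52), but its signals of 11.5 to 35.9 in 3 Yorkshire arrays lay below the 91.5 of the negative controls, so the size of its change is uncertain. The 10 macrophage markers had a median of 0.05, with LAPTM5 at 0.93 and AIF1 at 0.71, and the 5 lymphocyte markers a median of 0.11, with JCHAIN at 0.39 and CD8B at -0.18. Without Korean native pig 4, SLA-DQA1 was at 0.43, LAPTM5 at 0.24, AIF1 at 0.18 and JCHAIN at -0.33, and CD8B was at 0.16 without Yorkshire 3. Below 91.5 were also the signals of LAPTM5 in Yorkshire 3 (21.7), AIF1 in Yorkshire 1 (71.4), IRF9 in Korean native pig 1 (55.5), and CD8B in Korean native pig 4 (83.3) and Yorkshire 2 (85.3). JCHAIN was at 0.78 without Korean native pig 1 and CD8B at -0.36 without Yorkshire 2. Of 17 interferon response genes 14 were below 0, with a median of -0.20, although MX1 was at 1.00, and IRF9 was at -0.62, or -0.36 without Korean native pig 1 (adjusted p of the list = 0.377). MX1 signals of 65.7 and 71.7 in 2 Yorkshire arrays were also below 91.5. Without Korean native pig 4 the medians were -0.28 for MHC, -0.32 for macrophage and -0.37 for lymphocyte markers, and the interferon list was called lower (median -0.42, adjusted p = 0.0124). Other arrays moved calls too: without Korean native pig 3 the MHC list was called higher (median 0.37, adjusted p = 0.00544) and without Korean native pig 2 the macrophage list (0.46, adjusted p = 0.0436). The MHC median was -0.03 without Yorkshire 1, the lymphocyte median -0.04 without Yorkshire 2 and 0.37 without Korean native pig 2, and the interferon median 0.02 without Korean native pig 3. Within the bright and the dim arrays the medians were 0.03 and 0.45 for MHC, -0.25 and 0.51 for macrophage, -0.33 and 0.33 for lymphocyte markers and -0.37 and 0.11 for the interferon list.

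The list of pig growth and meat quality genes had a median of -0.39, with 11 of 16 below 0 (adjusted p = 0.149), or -0.19 without Yorkshire 3. PPARGC1A at -0.96 (-0.49 without Yorkshire 3) and HMGA1 at 0.52 had the lowest p, followed by PRKAG3, a muscle subunit of AMP-activated kinase, at -0.58 and SCD, the stearoyl-CoA desaturase, at -1.37 (SE 0.83). For SCD the spread between arrays was wide, with a signal of 3082 ± 3825 in Korean native pigs and 5531 ± 3330 in Yorkshire pigs (SD, n = 4). Its log2 change was -0.63 without Korean native pig 3 and -2.16 without Korean native pig 1.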

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

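Tests chosen after the results they bear on were seen were the counts of splits for probe sets, genes and unadjusted p, the labelling test for missing calls, the test of CREM and NR4A3 without the arrays of weak 5' signal, which replaced a covariate test unable to move the difference, as the covariate was balanced over the breeds, and the test of fibre share.

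The absence of calls came first, with 0 probe sets and 0 genes at the adjusted threshold by limma and 570 probe sets at an unadjusted p under 0.05, which leaves open breed or age differences too small to detect. The splits of the arrays cannot test the counts of 0, which all 35 must reach (35 for probe sets, most elsewhere 1, and 35 for genes, most elsewhere 0), but chance cannot be excluded for the others: of the 35 splits, 20 gave 570 or more at an unadjusted p under 0.05 (most elsewhere 1680), and 29 gave at least the 4 lists called by camera (most elsewhere 12). The count of 1680 came from Korean native pigs 1, 3 and 4 with Yorkshire 3, and the split between bright and dim hybridisation controls gave 1678 with 0 passing. Counts several times the real one point to a structure of the arrays, whose source was not tested, and with the hybridisation controls as a block 0 probe sets passed between breeds. Uneven labelling length may hide differences, as 2 arrays had weak 5' signal. Without them, or with the 3' to 5' ratio as a covariate, 0 passed. With the covariate 756 were at an unadjusted p under 0.05, a count that varied widely between splits and so decides nothing. Without the arrays there were 614, inside the range of 382 to 1321 of the other 9 splits of those 6 arrays, which leaves this open. The bound was tightened after 614 was seen. Under the earlier bound, at or below the median of 655, this explanation would have been excluded.

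CREM and NR4A3 were lower by a mean of -2.45 log2 units in Korean native pigs without passing, except NR4A3 with the replicate number as a block (adjusted p = 0.00943). Whether the numbers pair single arrays could not be settled, and they follow the brightness of the hybridisation controls. Of the 35 splits, 6 gave a smallest limma p as low as that of CREM, 1.95e-05 (lowest elsewhere 3.12e-06), so chance cannot be excluded. This count concerns CREM alone, as the limma p of NR4A3 was 6.12e-05. The 2 arrays of weak 5' signal came from different breeds, and neither gene overlapped between breeds, so the difference had to stay negative without them. Its size could fall, and 82.4% of it was left (SE 11.3), so most of it did not rest on these arrays. This SE and the next take the 2 genes as independent and the main value as exact, so both may be too small. Brightness of the hybridisation controls was balanced over the breeds, so a brightness effect shared by the breeds could not have produced the difference. The within-batch differences had to be negative, since neither gene overlapped between breeds, and to average to the main value. They therefore cannot test brightness as a cause. The smaller of them, in the dim arrays, was 76.8% of the main value (SE 13.7). A wider response to muscle activity or adrenergic drive before slaughter may lie behind the lower CREM and NR4A3, and stays open. The 10 tested genes of a list of 20 activity-responsive genes, written after CREM and NR4A3 were seen, had a mean of -0.19 (SE 0.21). Of these, 5 were above and 5 below 0, and 21 of the 35 splits were as far from 0. Below 0 were XIRP1 (-1.455), ATF3 (-0.83), ANKRD1 (-0.73), TFRC (-0.32) and KLF10 (-0.16). Above 0 were CHRNA1 (0.73), CITED2 (0.48), VEGFA (0.24), NR4A2 (0.09) and MYC (0.05). The mean took all genes with the same sign, whichever way each responds to activity, so it cannot decide. Breed, age and chance all remain open for this pair.

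The lower fast fibre and glycolysis lists depended on single arrays and on scaling. Their means per array differed by -0.314 and -0.263 between breeds (exact permutation test, two-sided p = 0.171 and 0.2, both 0.833 when adjusted over the lists). Chance therefore cannot be excluded for either list. The mean of both medians was 41.7% of its value without Yorkshire 4 and 57.0% without Korean native pig 3, and quantile normalisation gave medians of -0.01 and -0.13. Within the bright arrays they were -0.02 and -0.04 against -0.61 and -0.57 within the dim ones. The dim arrays include Yorkshire 4, so brightness cannot be told apart from that array here. With brightness as a block both lists kept their camera calls (adjusted p = 0.00361 for each), but a balanced block cannot move the medians. A lower share of muscle fibres in the Korean native pig pieces could raise the markers of other cell types alike, but the collagen and matrix list was also lower. Its mean per array differed by -0.26 (exact permutation test, two-sided p = 0.171), which cannot decide. The bound first written was a camera call, which the list met at an adjusted p of 0.00351, and it was replaced after that was seen because camera called 4 or more lists in 29 of the 35 splits.

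Within the 4 arrays of a breed, single arrays stood apart from the other 3 in 14 of 178 sets of values tested. Dixon's test marks about 1 in 20 groups by chance, or about 8.9 here. All values are log2, and those of genes are log2(signal + 32). DHDH was low in Korean native pig 3, at 7.08 against 8.62 to 8.75, and high in Yorkshire 3, at 9.77 against 9.50 to 9.54. LDHA was 16.6 in Yorkshire 4, against 16.14 to 16.21, and ELOVL6 was 9.10 in the same array, against 11.40 to 11.47. In Yorkshire 3, EGR1 was 9.62 against 8.15 to 8.39, MBP was 7.79 against 8.94 to 9.03, and PRKAG3 was 7.75 against 8.55 to 8.69. S100B was 8.38 in Korean native pig 3, against 8.84 to 8.92. The mean of the citrate cycle list was 11.81 in Yorkshire 1, against 12.01 to 12.03, and that of the immediate early list was 9.04 in Yorkshire 2, against 9.93 to 10.02. In Yorkshire 4 the mean of the ribosomal protein list was 14.97, against 14.51 to 14.58, and that of the smooth muscle and pericyte list 10.28, against 10.45 to 10.48. Korean native pig 1 stood apart in the 3' to 5' ratio of the spiked controls, at 4.32 against 1.31 to 1.56, and in the 18S ribosomal RNA control, at 11.68 against 9.01 to 9.26.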

How the results depend on the processing

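Settings with the hybridisation block, the 3' to 5' covariate, both high-ratio arrays left out, the ranking among splits and the count at an unadjusted p under 0.05 were chosen after the data were seen. By limma the counts of probe sets, probe sets of 1.5-fold and genes were 0 under all settings run except the replicate block, which gave 1 for each, NR4A3 (adjusted p = 0.00943, lower). Same-numbered arrays deviated together with r of -0.04, 0.31, 0.10 and 0.05. Korean native pigs 2, 3 and 4 and Yorkshire 2 matched their own number best, and the other arrays did not. This neither shows nor excludes that the numbers pair single arrays. The numbers do follow the brightness of the hybridisation controls, and every best match lay within the same brightness, so the replicate block also holds that structure. With brightness alone as a block the smallest adjusted p was 0.320. The replicate block added a call for the slow fibre list (0.0468). The number of probe sets at an unadjusted p under 0.05 was 1074 without a filter, where more probe sets were tested, and 452 to 695 with 1 array left out. Camera called 2 lists with quantile normalisation, 0 with an estimated correlation, 0 by fry, 0 by rank among the splits, and 2 to 6 with 1 array left out. Besides arrays left out and the other list tests, the respiratory chain call was lost with the larger value added before log2 (0.0534), no filter (0.0626), quantile normalisation (0.112), median centring (0.134), eBayes without trend (0.115), the covariate (0.0576), both high-ratio arrays left out (0.149) and the mean over probe sets (0.102). Array weights called MHC (0.00188) and macrophage markers (0.00850), and leaving out both high-ratio arrays called fatty acid synthesis (0.0190). Directions changed as follows, and the cause was not tested. Median centring gave 0.0320 for the citrate cycle and 0.0274 for growth, and moved the median of all changes to 0.0805. Quantile normalisation gave -0.00937 for fatty acid oxidation and -0.00374 for endothelial markers. Array weights gave -0.0423 for fatty acid oxidation and 0.222 for the clock list. Leaving out both high-ratio arrays gave 0.0426 for growth, -0.0365 for ribosomal proteins, 0.138 for the clock list and 0.167 for CD8B. Smooth muscle markers were at -0.113 without a filter and -0.256 by the mean over probe sets. With 1 array left out, ranges crossing 0 were -0.113 to 0.0207 for the citrate cycle, -0.126 to 0.107 for fatty acid oxidation, -0.0753 to 0.0575 for growth, -0.00707 to 0.167 for ribosomal proteins, -0.204 to 0.0109 for heat shock, -0.297 to 0.192 for the clock list, -0.0450 to 0.233 for glucocorticoid response, -0.283 to 0.370 for MHC, -0.421 to 0.0248 for interferon, -0.318 to 0.459 for macrophage, -0.371 to 0.367 for lymphocyte, -0.0870 to 0.0592 for endothelial, -0.0300 to 0.171 for smooth muscle and -0.205 to 0.324 for nerve markers. For genes they were -0.326 to 0.777 for JCHAIN and -0.361 to 0.161 for CD8B. Genes near the filter level have signals close to the negative controls, which limits what their changes show.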

Other observations

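The values here were chosen after they were seen, and no explanation was tested. Korean native pig 4 carried high levels of immune transcripts. Its mean log2 signal was 10.01 over the macrophage markers, against 7.73 to 8.32 in the other Korean native pigs and 7.90 to 8.63 in Yorkshire pigs. Over the lymphocyte markers it was 8.98, against 7.11 to 7.67 and 7.29 to 7.96, and over the MHC list 11.16, against 9.42 to 9.90 and 9.60 to 10.18.

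Signals of SCD and ELOVL6, 2 of the 11 tested genes of fatty acid and triglyceride synthesis, varied widely between animals of a breed. The signal of SCD was 8733 in Korean native pig 1 and 336.1 to 1947 in the other Korean native pigs, and in Yorkshire pigs it was 1170 in replicate 4 and 5332 to 9194 in the others. ELOVL6 was 3388 in Korean native pig 1, against 175.1 to 770.0 in the others of that breed, and 518.4 in Yorkshire 4, against 2672 to 2809.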
